A study of Oryza sativa with 6 samples.

How the data were processed

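Poly(A) mRNA of mature rice leaves was sequenced in 6 libraries, 3 from wild-type plants (WT) and 3 from the mutant line osatg5-1. The plants grew in a field under natural long days, and leaves were taken at tillering, the stage at which the plant forms side shoots. Per the labels' protocols, RNA was extracted with a column kit and libraries were made with a stranded mRNA kit that uses random hexamer priming. Each library was put in its genotype and given its replicate number from its title. The labels do not say whether replicates came from separate plants, so p-values measure only the spread between these samples, which may be technical.

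The authors deposited a table of raw counts per locus, with 1 column per library and no pooling. They also deposited FPKM values for the same loci, 1 file per library, scaled by gene-model length and library depth, per the file headers. The submitters' processing notes name HISAT2 and the genome build IRGSP-1.0. The counting tool, its strand setting and the annotation release are not given in the sources used here, so reads of overlapping, antisense or near-identical loci may be split between them. The tables hold 57839 loci. Of these, 55801 carry a LOC_Os number, 1853 are transcripts labelled newGene and 185 are models on ChrSy or ChrUn sequences. FPKM is 0 exactly where the count is 0. In every library a count of 2 was 2.59 to 2.83 times as frequent as a count of 1, so the counts do not behave like single read pairs, and single counts are not independent molecules. Counting floors (3 counts) and exact binomial (Clopper-Pearson) 95% intervals therefore cover counting error only.

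The totals ran from 30927816 to 39351357 counts per library, at which 3 counts correspond to 0.0762 to 0.097 CPM (counts scaled to the library total). Loci that pass edgeR's filterByExpr, 23074 in all, were tested with edgeR's quasi-likelihood test (version 4.0.16 in R 4.3.3) after TMM scaling, with genotype as the only term and Benjamini-Hochberg adjustment. A locus is called at an adjusted p under 0.05. CPM values in the text are TMM-normalized unless stated. The standard error of a log2 fold change was taken as its size divided by the square root of the F statistic. Where all libraries of a genotype had 0 counts, a lower bound of the fold was taken from pooled counts against a floor of 3 counts over that genotype. If both mates of a read pair were counted, which the frequency of counts of 2 leaves open, 3 pairs give 6 counts and each bound is 0.5 times as large. On counts simulated from the real means, depths and dispersions over 23074 loci, with 200 changed loci, the test recovered 73% of 2-fold and 90% of 4-fold changes in the right direction. Of the 180 calls in the simulation, 9.44% were false, above the nominal 5%. The simulation was a single draw with far fewer changed loci than the data have calls, and all its changes were 2-fold or 4-fold. Its shares therefore need not carry over to the calls reported here.

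Positions were taken from the LOC_Os numbers, which give the chromosome and run along it; no coordinates were used. The share of called loci in windows of 100 consecutive tested loci, and the number of direct neighbours called in the same direction, were compared with 100000 permutations of the calls over the 21967 placed loci that were tested. These permutations give one-sided p-values, and both steps found no excess in randomly placed calls and an excess in a planted block. The length of a locus is the one implied by its counts and FPKM.

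The files pair no locus with a gene name. The name table used here, made from another assembly (ASM3414082v1), matched 1 of the 57839 IDs, through a synonym. The 47 gene lists fixed before the data were examined use other identifiers or product names, and 0 of their 127 IDs are in the files. OsATG5, the flowering, clock and autophagy genes and all other lists, including those for other cell types, are therefore not analysed here, and no gene name was inferred from an ID. Besides OsATG5 and members of the lists, the rule for naming loci was to give the 8 highest and 8 lowest fold changes among called loci with at least 5 CPM on average, no overlap between the genotypes and a product name. No product names could be matched, so the rule was applied without that condition and only the first 2 in each direction are given by ID. The comparison of the genotypes, its test, the window test along chromosomes and the first group of alternatives were chosen before the data were examined. These alternatives were RLE scaling, library-size scaling, no filter, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom (limma 3.58.1), a replicate block, a test against a 1.5-fold change and leaving out each library. For the window test they were windows of 50 and 200 loci and calls at an adjusted p under 0.01. Chosen after the data had been seen were limma on log2(FPKM + 1), placed loci alone, thinning to the smallest library, removal of each library's trend over locus length, leaving out each chromosome and the floor of 6 counts. The descriptions of abundance classes, locus length, the 100 most abundant loci, newGene transcripts, loci read in 1 genotype alone, single chromosomes and neighbouring loci were also chosen after the data had been seen.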

Results

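The series asked how loss of autophagy bears on flowering time in rice, and compared mature leaves of the mutant osatg5-1 with those of wild-type plants at tillering. ATG5 is a core protein of autophagy, the pathway by which cells carry their own constituents to the vacuole for breakdown. The 3 WT libraries held 31628507, 31677943 and 30927816 counts, and the 3 osatg5-1 libraries held 31296258, 36280885 and 39351357. Between 27632 and 28437 loci had at least 1 count in a library. The 10 most abundant loci took 9.40% to 10.1% of the counts in each library, and newGene transcripts took 1.10% to 1.20%.

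Leaves of the same genotype resembled each other more than leaves of the other genotype. The correlation of log2 CPM across loci was 0.980 to 0.985 for the 6 pairs of libraries within a genotype and 0.956 to 0.966 for the 9 pairs across genotypes. Loci are not independent replicates, so these values only describe the libraries. The first principal component held 56.3% of the variance and placed the 3 WT libraries between -55.8 and -41.3 and the 3 osatg5-1 libraries between 46.3 and 47.9. The counts of every pair of libraries differed by more than counting error, with a chi-square per degree of freedom of at least 10.3, so no pair was counted as 1 sample. This value covers counting error only and treats single counts as independent, so it does not show whether replicates were separate plants or technical repeats.

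The mutant leaf transcriptome differed from wild type at 3793 loci, 16.4% of the 23074 tested, in nearly equal numbers each way. Transcripts of 1899 loci rose in osatg5-1 and those of 1894 fell (edgeR quasi-likelihood test, adjusted p under 0.05, n = 3 libraries per genotype). Most changes were small. The median called rise was 1.66-fold and the median called fall 1.52-fold, also with the 35 and 4 loci at 0 counts in a genotype put at their lower bounds, and 699 loci rose and 482 fell by 2-fold or more, or 642 and 474 without loci that had 3 or fewer counts over all libraries of a genotype. The 2 genotypes did not overlap at 35.4% of tested loci, where chance gives 10%. Against a null of up to 1.5-fold, 393 loci rose and 327 fell. The share of higher calls went with the zero point that each setting gave the fold changes. It was 50.1% with TMM scaling, where the median log2 fold change over tested loci was 0.00162. With library-size scaling it was 58.4% (median 0.0381), and with each library's trend over length removed 42.6% (median -0.0324). That last correction also removes each library's mean level, so the fall to 42.6% cannot be put down to length alone. The near-even split therefore depends on the scaling. Limma on log2(FPKM + 1), which differs in unit, scaling and test, called 2284 higher and 1431 lower loci, or 61.5% higher.

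**Figure D1:**
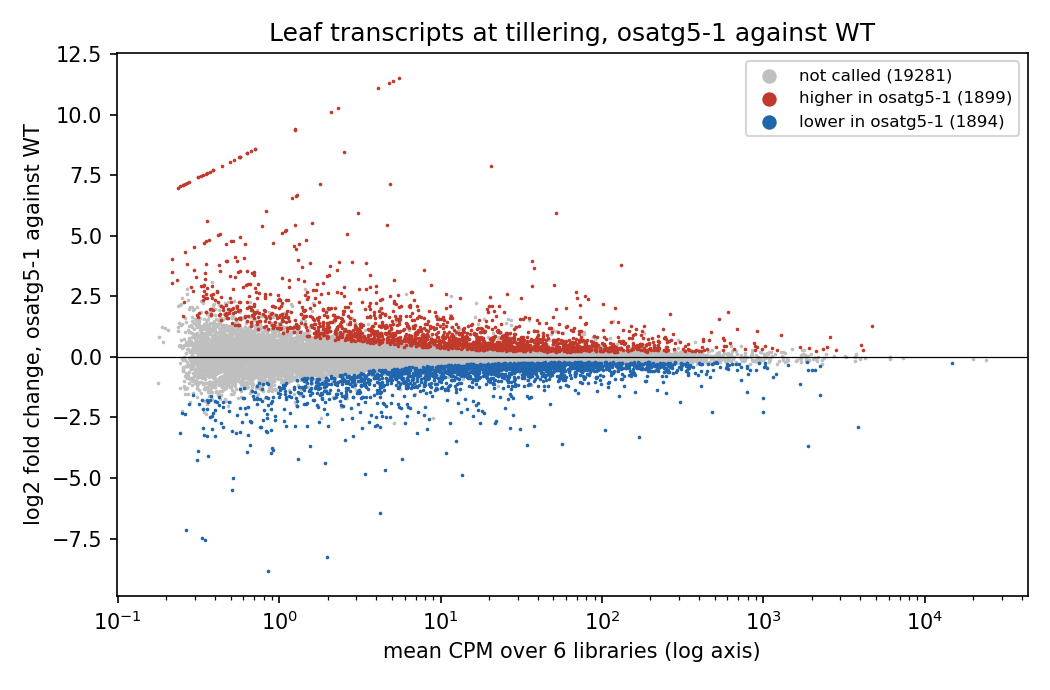
Log2 fold change of osatg5-1 against WT (vertical axis) against mean CPM over the 6 libraries (horizontal log axis) for the 23074 tested loci, 1 point each. The 1899 higher loci are red, the 1894 lower loci blue and the others grey; the rising line of red points at the upper left holds loci with 0 counts in all WT libraries, whose fitted fold changes depend on the prior count.

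Large changes leaned towards higher expression in the mutant. At 4-fold or more, 256 loci rose and 139 fell, or 199 and 131 without those near-empty loci. At 16-fold or more, 75 rose and 16 fell, or 20 and 8 without them. Among rarely read loci, with under 1 CPM on average, 214 rose and 99 fell. Among loci of 100 CPM or more, 192 rose and 273 fell, with median changes of 1.33-fold and 1.31-fold. Direction also went with the length of the locus. In the shortest of 4 equal length classes, of up to 1335 bases, 501 rose and 380 fell, whereas 372 rose and 588 fell in the longest, of 2727 bases or more (odds ratio 2.08, 95% interval 1.72 to 2.52, Fisher's exact test over loci, two-sided p = 7.63e-15). Fisher's tests over loci, here and below, treat loci as independent and leave out the spread between libraries. With each library's own trend over length removed, a correction built to take out such a lean, 398 rose and 554 fell in the shortest class (41.8% higher) and 443 rose and 553 fell in the longest (44.5% higher), against 56.9% and 38.8% higher without it. Each library's trend over length was taken on log2 CPM relative to the mean of each locus over the 6 libraries. These relative trends varied between libraries of 1 genotype, from -0.0217 to 0.063 per doubling of length in WT and from -0.041 to -0.0147 in osatg5-1 (exact permutation test, two-sided p = 0.30, n = 3 and 3, smallest possible 0.1).

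Abundant leaf transcripts were called more often than others, and a few changed greatly. The 100 most abundant loci took 24.7% to 26% of the counts of a library, and 14 of them rose, 17 fell and 69 were not called. These 31% called compare with 16.4% of the other tested loci, a difference that was not tested. Over all tested loci the called share rose from 9.35% under 1 CPM to 27.4% at 100 CPM or more. Median called rises shrank from 4.95-fold to 1.33-fold between these classes, and median falls from 4.64-fold to 1.31-fold. The higher share may thus only reflect that small changes are more readily called at high counts. A locus on chromosome 1 that ranked 5 in WT fell from 6853 ± 545 to 914 ± 119 CPM (SD, n = 3 each) and ranked 110 in osatg5-1, a log2 fold change of -2.91 ± 0.11 (SE). A locus on chromosome 5 fell from 3521 ± 347.5 to 276 ± 90.9 CPM, or -3.67 ± 0.20 on the log2 scale. Another on chromosome 1 fell from 3379 ± 769 to 1140 ± 100.2 CPM, and one on chromosome 7 from 2313 ± 183 to 1052 ± 14.4 CPM. The only rise of 2-fold or more in this group was at a locus on chromosome 12, which went from 2785 ± 155 to 6671 ± 259 CPM and from rank 19 to rank 5. The largest adjusted p of these 5 loci was 8.33e-05 (edgeR quasi-likelihood test). These loci were chosen after their values were seen, and reads they share with near-identical copies would count for either.

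The largest rises under the naming rule were at loci with no count in any WT library. LOC_Os03g56930, on chromosome 3, was at 0 counts in all 3 WT libraries and at 19.0, 8.86 and 5.25 CPM in the mutant libraries, at least 334-fold higher against a floor of 3 counts over the WT libraries, or 167-fold if both mates of a pair were counted and the floor is 6 counts (adjusted p = 0.000344, edgeR quasi-likelihood test). LOC_Os11g31630, on chromosome 11, was likewise at 0 counts in WT and at 10.1 ± 1.60 CPM in osatg5-1 (SD, n = 3), at least 319.6-fold higher, or 159.8-fold with the floor of 6 counts (adjusted p = 5.08e-06, edgeR). The largest falls were at LOC_Os09g23300 on chromosome 9, from 26.2 ± 6.83 to 0.903 ± 0.215 CPM, and at LOC_Os04g35030 on chromosome 4, from 10.98 ± 2.21 to 0.574 ± 0.454 CPM. Their log2 fold changes were -4.87 ± 0.23 and -4.23 ± 0.38 (SE; edgeR adjusted p = 1.99e-06 and 8.16e-05). The single locus matched to a gene name, LOC_Os01g19850 (OsCCC2, also KCC2, a cation-chloride cotransporter), was at 1.75 ± 0.458 CPM in WT and 1.46 ± 0.319 CPM in osatg5-1, a log2 difference of -0.27 ± 0.29 that did not pass the test (edgeR adjusted p = 0.58).

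**Figure D2:**
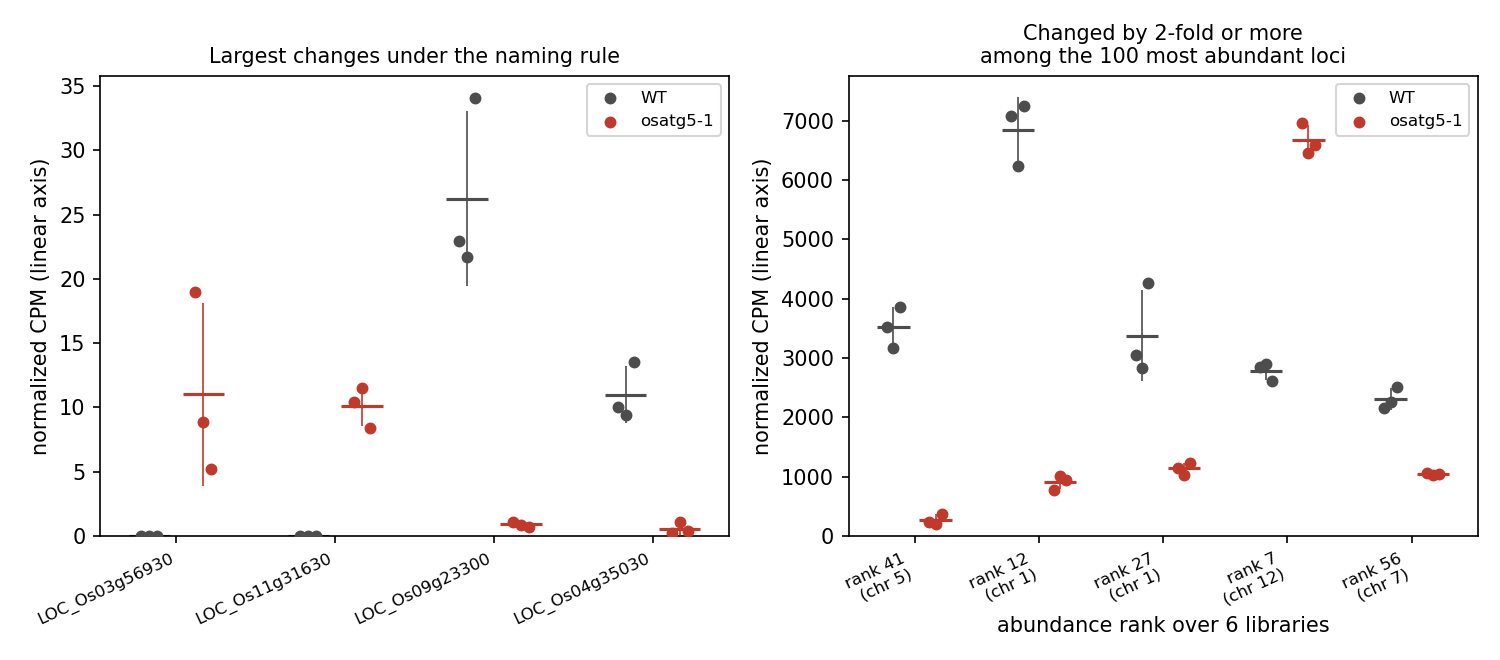
TMM-normalized CPM (linear axes) in each library, 1 point per library, with the mean (bar) and SD (line) of 3 WT libraries in grey and 3 osatg5-1 libraries in red. On the left, the 2 named rises start from 0 in WT and the 2 named falls end near 0 in osatg5-1; on the right, 4 of the 5 loci changed by 2-fold or more among the 100 most abundant fell.

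Expression confined to 1 genotype was almost one-sided. At 12 loci every osatg5-1 library held at least 1 CPM of its total counts while all 3 WT libraries had 0 counts, and 1 locus showed the reverse. All 13 were called. The mutant-only loci were at a median of 3.34 CPM and at most 11.03 CPM, at least 33.2-fold to 334-fold higher by locus, or 16.6-fold to 167-fold with the floor of 6 counts. Of the 12, 11 carry LOC_Os numbers on 7 chromosomes, with no more than 2 on any chromosome, and 1 is a newGene transcript, as is the WT-only locus. The numbers were 23 and 1 at a threshold of 0.5 CPM, and 7 and 0 at 2 CPM. Without osatg5-1 replicate 1, which only relaxes the rule, they were 13 and 2.

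Transcripts labelled newGene were called less often than other loci. Of the 1083 newGene transcripts tested, 57 rose and 68 fell, or 11.5% (odds ratio 0.652 against all other loci, Fisher's exact test over loci, two-sided p = 4.46e-06, 1 of 2 such tests). Without osatg5-1 replicate 1 or replicate 3, 82 and 81 of them were called, while calls over all loci fell from 3793 to 2812 and 2567. The newGene transcripts took only 1.10% to 1.20% of the counts of a library. Over all tested loci the called share rose with abundance, from 9.35% under 1 CPM to 27.4% at 100 CPM or more. The test was not adjusted for abundance, so it does not separate the newGene label from low abundance. Of 24 models on unplaced sequences, 1 fell (odds ratio 0.221, Fisher's exact test, p = 0.163).

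Changed loci lay on all 12 chromosomes, at shares from 14.7% on chromosome 2 to 18.8% on chromosome 7. No chromosome passed a test against the rest (Fisher's exact test over loci, 12 tests, smallest adjusted p = 0.0792). The densest window of 100 placed loci lay on chromosome 6, between the places 1146 and 1245 of its 1776 tested loci, with 11 higher and 22 lower loci. Its 33% of called loci, against 16.7% over the genome, did not pass the test (permutation test, one-sided p = 0.0998). In windows of 50 loci the highest share was 46%, also on chromosome 6 (permutation p = 0.00633), and with calls at an adjusted p under 0.01 it was 25% of 100 loci (permutation p = 0.00114, same chromosome). With chromosome 6 left out, the highest share in windows of 100 loci, with calls at an adjusted p under 0.05, was 29% (permutation p = 0.863). The settings that passed were not run without chromosome 6.

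**Figure D3:**
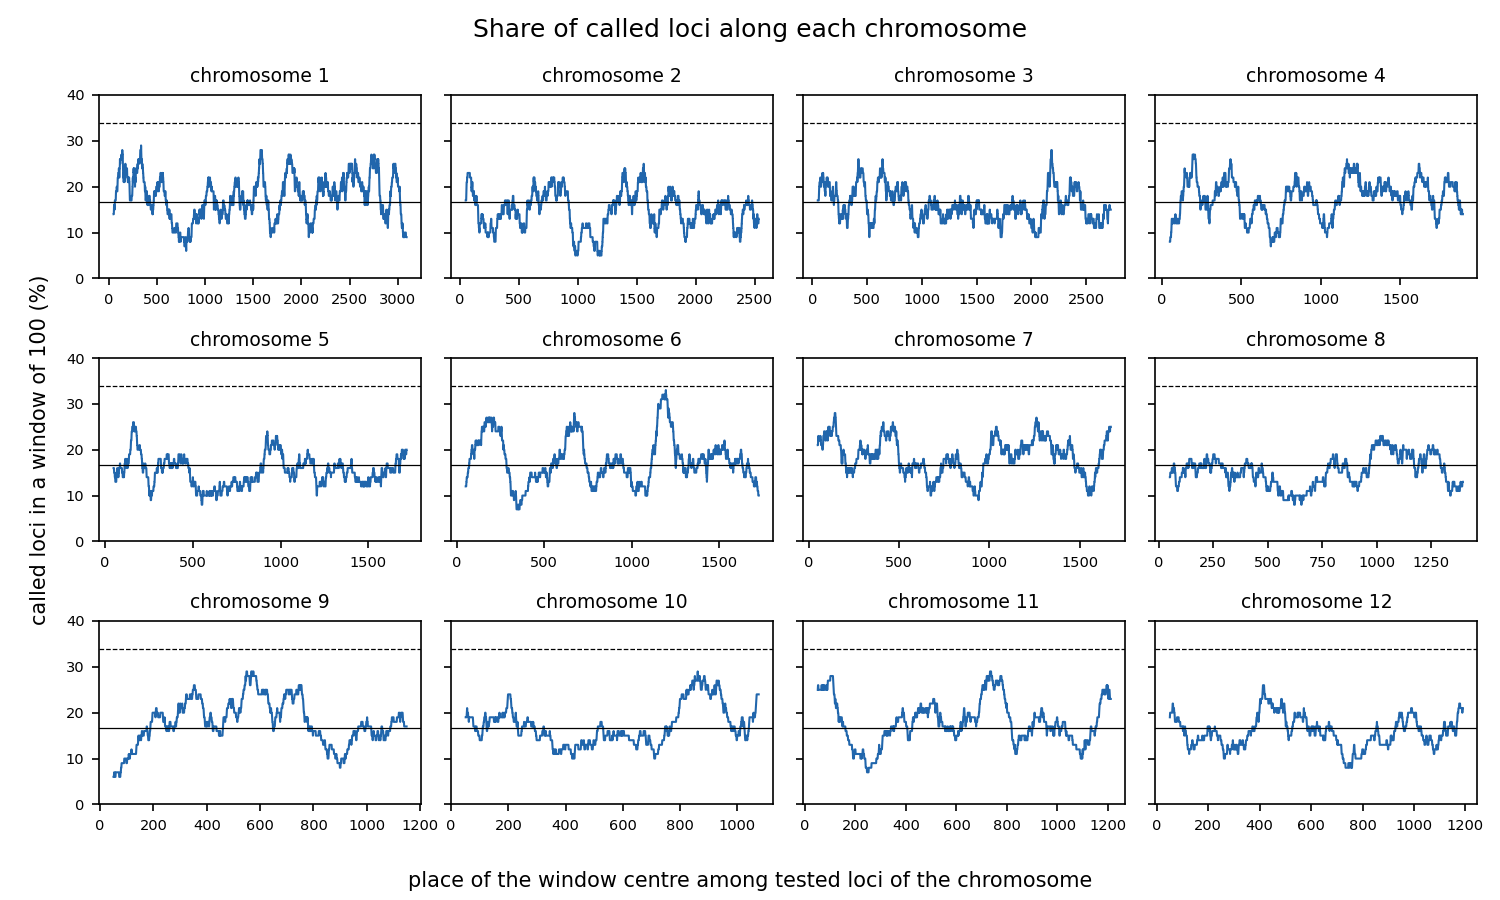
Percent of called loci in sliding windows of 100 consecutive tested loci (vertical axis) along the 12 chromosomes, by the place of the window centre among the tested loci (horizontal axis). The solid line marks the share over all placed loci, 16.7%, and the dashed line the upper limit of the central 95% range of the highest window in permuted genomes, 34%; the highest window, on chromosome 6, reached 33%.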

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

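Limma on log2(FPKM + 1), placed loci alone, thinning, the length trend, each chromosome left out, and the alternatives for loci read in 1 genotype and for neighbours were chosen after the data had been seen. The count of 3793 changed loci stayed within 1.5 times under each alternative but 1: it ranged from 3638 to 4067 over the other scalings, filters, tools and corrections, and from 2567 (without osatg5-1 replicate 3) to 3500 (without WT replicate 3) when 1 library was left out. The exception was the test against a 1.5-fold change, with 720 loci, 393 higher and 327 lower, which by its construction passes only larger changes. The higher loci ranged from 1281 to 1828 and the lower ones from 1286 to 1672 with 1 library left out. Without osatg5-1 replicate 3, 2448 of the 3793 loci were still called; with DESeq2, which called 3987 and gave no adjusted p at 5700 loci, 3519 were, and all of them in the same direction. The share of higher loci among the called was 50.1%, 58.4% with library-size scaling, 61.5% on log2(FPKM + 1) and 42.6% with each library's trend over length removed. The last of these also shifted the median log2 fold change from 0.00162 to -0.0324, so its share does not reflect length alone. With the replicate block 3765 loci were called, 3405 of them shared; the numbers were not treated as pairs, because same-numbered libraries deviated together with correlations of only 0.0281, -0.0267 and 0.0878. The 4 named changes kept their direction and their call under each alternative run for that count. With limma on log2(FPKM + 1), 305 loci rose and 169 fell by 2-fold or more, against 699 and 482. The added 1 shrinks fold changes at low FPKM by construction. LOC_Os04g35030, for example, went from -4.233 to -1.975 on the log2 scale. How much of the drop in numbers comes from this was not tested. Mutant-only loci numbered 23 at 0.5 CPM and 7 at 2 CPM, WT-only loci 1 and 0. With 1 library left out they numbered 13 to 16 and 1 to 2. Leaving out a library only relaxes the rule, so these numbers could not fall and say nothing about stability. The densest window passed the test with 50 loci (46%) and at an adjusted p under 0.01 (25%), but not with 100 or 200; the cause was not tested. Direct neighbours called in the same direction stayed above chance under each alternative run for them, at 1.501 to 2.541 times; loci 2 to 5 and 6 to 20 places apart exceeded chance 1.161 and 1.051 times. Tests of the targeted gene and of the flowering, clock, autophagy and other lists, and the window test without the chromosome of OsATG5, were not run because no list member could be matched to an ID; each chromosome was left out in turn instead. Loci near the filter rest on few counts, and at this depth a locus with 0 counts is only known to lie below 0.0762 to 0.097 CPM in a library, or 0.152 to 0.194 CPM if both mates were counted.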

Other observations

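The tests in this part were chosen after the main comparison had been seen, including the tests of neighbours, of loci read in 1 genotype and of locus length; the other splits of the libraries were also added then. Neighbouring loci changed together. Among direct neighbours along a chromosome, 503 pairs were called in the same direction against 305.8 expected by chance (1.65 times, permutation test, one-sided p = 1e-05, the smallest that 100000 permutations can give), while 219 pairs were called in opposite directions against 305.9 expected. There were 16 runs of at least 4 neighbours called in 1 direction, 7 higher and 9 lower. The longest was a run of 9 tested loci on chromosome 9, all lower in osatg5-1, by 0.66 to 1.46 on the log2 scale.

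Similar abundance of neighbours does not account for these pairs, since permuting calls within 10 classes of abundance left the ratio at 1.64 (permutation p = 0.0001, the smallest that 10000 permutations can give). Reads shared between overlapping or read-through neighbours are argued against as the whole cause. Loci 2 to 5 places apart exceeded chance 1.16 times (permutation p = 0.0001), or 1.10 to 1.22 times against the limits of the central 95% of permuted counts. Direct neighbours whose locus numbers lie more than 20 apart did so 1.501 times (1.245 to 1.886 against such limits, permutation p = 0.0001). These ranges hold the spread of permuted counts only, not that of the observed pairs or of the libraries. Reads shared among tandem copies of a gene, co-regulated clusters and blocks of differing genetic background, which the labels do not describe, were not tested and may each contribute.

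The excess of mutant-only loci is a second pattern. Thinning every library to the smallest total moved neither number (12 and 1, lower 95% bound of the ratio 1.775). The lower bound stayed above 1, which was the limit written beforehand for this test. The test could hardly have come out otherwise, so it does not decide whether the greater depth of 2 mutant libraries contributes. The criterion of 1 CPM is already relative to the library total. The WT libraries, at 30927816 to 31677943 counts, lay at or near the smallest total, so thinning removed few of their counts. The comparison also rests on 1 thinning, and the bound covers counting error only. A single linked block does not hold all of them, since the 11 placed loci lie on 7 chromosomes; the limit first written for this test, an upper 95% bound under 50% for the fullest chromosome, was not met at 51.8%, and the number of chromosomes was used after both values had been seen. The other 9 splits of the 6 libraries gave at most 0 such loci against 13 in the real one. Each of those 9 splits put both genotypes in each group, so none of the 13 loci could count in them. The comparison therefore decides nothing about chance, and 10 splits are too few for a share under 0.05 (1 of 10 was as large). Differences of genetic background spread over the genome, silent loci read in the mutant and the mutation itself remain open and were not tested.

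The lean of short loci to higher and long loci to lower expression is the third pattern. Lower abundance of short loci does not account for all of it among these calls. Within abundance, the shortest length class had the larger share of higher calls in 3 of 4 classes, by 15.6 to 18.3 percentage points (largest of 3 Fisher's exact p = 0.00489). These tests treat loci as independent and leave out the spread between libraries. In the class under 1 CPM the shares were 70.7% and 70.8%, so the first criterion, a larger share in all 4 classes, was not met, and the size of the differences within classes was used after they had been seen. RNA fragmentation or size selection of whole libraries and a genotype effect on long transcripts both stay open. The slopes over length, of log2 CPM relative to the mean of each locus, averaged 0.0246 in WT and -0.0246 in osatg5-1. Subtracting that mean makes these averages equal and opposite by construction. The slopes overlapped through WT replicate 3 alone, and 3 libraries against 3 are too few to decide (exact permutation test, p = 0.3, smallest possible 0.1). Removing each library's trend ended the lean (41.8% higher calls in the shortest class and 44.5% in the longest), which the correction does by construction whatever the source of the trend.

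For the count of changed loci, the other 9 splits of the 6 libraries called at most 0 loci (edgeR quasi-likelihood test) against 3793 in the real one. At an unadjusted p under 0.05 they gave 334 to 922 loci against 7003. Each of those 9 splits put both genotypes in each group, so any genotype difference widened the spread within groups and lowered the calls. They therefore give no baseline for chance. Other tools were not run on them, and 10 splits are too few for a share under 0.05 (1 of 10 was as large). With each library's own trend over length removed, 4067 loci were called, and 3508 of the 3793 were among them. The correction also shifted the zero point of the fold changes, which may have moved calls either way. The trend thus does not account for most of these changes. This reading of the correction was made after its result had been seen.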
